A study of Mus musculus with 12 samples.

How the data were processed

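RNA was measured by sequencing of polyadenylated transcripts from distal ileal tissue of BALB/c mice, an inbred laboratory strain. The labels give 12 samples, 6 that received phosphate-buffered saline (PBS) and 6 treated with Porphyromonas gingivalis. Tissue was kept in an RNA stabilising solution, RNA was purified on columns and libraries were made with an Illumina TruSeq RNA kit, per the labels' protocols. The route, dose and duration of the treatment are not given in the sources used here, nor is it stated whether each library came from a different mouse. The p-values below therefore measure the spread between these samples.

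The submitters' processing notes name FastQC, HISAT2, Cufflinks and DESeq2 and the mouse genome build GRCm38 (mm10), without versions or roles. The counting method, the strand setting and the annotation release are not given in the sources used here. Overlapping and antisense genes, and genes with near-identical copies such as globin, defensin, interferon-induced GTPase and immunoglobulin genes, are therefore uncertain. The deposited table holds 45808 genes by symbol, and its values are a normalized signal: gene counts that the authors divided by 1 size factor per sample, read from the file name and from the values themselves. In every sample the values were whole multiples of 1 step. Dividing by that step gave whole reads for 100% of values within a tolerance of 0.001 reads, with a largest deviation of 3.69e-05 reads. The floor of 3 reads given for a count of 0 covers counting error only. The recovered totals ran from 6553306 to 10378841 reads per library. No reads were recorded for 18583 genes. A further 27 gene names had been turned into dates, 2 of which occurred more than once, and 20 of them were tested but none is named. No 2 libraries were copies of each other, since the smallest chi-square per degree of freedom between any pair was 6.54.

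The groups were compared with limma 3.58.1 in R 4.3.3, with a mean-variance trend, on log2(normalized count + 1). Genes with a mean normalized count of at least 10 over the 12 samples were tested, which left 15025 genes, with two-sided tests and Benjamini-Hochberg adjustment at 0.05. The pseudocount of 1 makes log2 differences understate the change of weakly expressed genes. The median standard error of a log2 difference was 0.15. On data simulated from these libraries with 15025 genes, changes were put only into genes with a mean normalized count of at least 50. The same steps recovered 86% of 100 such genes changed 2-fold and 100% of 100 changed 4-fold, with 11 false calls. A simulated list of 20 genes shifted 1.5-fold was called, and 0 of 49 unshifted lists were. Genes were simulated independently of one another and these lists were drawn at random. The simulation therefore does not show how often lists whose members vary together are called falsely. Nor does it show what share of real changes is found below a mean of 50, or in genes that vary together across libraries. Scd1, for example, averaged 7502 ± 4217 in PBS and 573 ± 750 after P. gingivalis and did not pass (limma adjusted p = 0.165). In the real libraries the estimated correlation between members was 0.84 for the B cell list and 0.68 for the smooth muscle list.

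A total of 36 gene lists for ileal cell types, neighbouring tissues and pathways were tested with camera, using a preset correlation of 0.01 between genes, where at least 5 members passed the filter, which held for 35 lists. Camera with an estimated correlation, fry and an exact permutation of list means over all labelings of the samples were run beside it. The neutrophil list had fewer than 5 tested members and was left out. Principal components of the tested genes were compared by exact permutation.

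The named genes followed a rule. It took the 12 genes with the largest change in each direction among those past the threshold with a mean of at least 50. As fewer than 5 passed, it took instead the 6 in each direction with the smallest p, named as not passing. It added the 4 members with the smallest p of each called list, up to 2 members of other lists that passed over the list alone, and a set of inflammatory, antimicrobial and barrier genes. Lists, tests, this rule and the alternatives listed last were fixed before the data were examined. Added later were a gut position score as a covariate, leaving out libraries at the ends of that score or with much 18S ribosomal RNA, the exact permutation of list means, and the comparison of spread between libraries. Mesothelial, fat cell identity, lipid synthesis, gut position and glucocorticoid target genes were chosen after the values were seen, as were Apoc1, Rn18s-rs5, Gm10800, Alb and the mitochondrial ribosomal RNA. The fat cell identity genes were taken from the adipocyte list fixed beforehand.

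Alternatives fixed beforehand were other pseudocounts and filters, trimmed-mean and upper-quartile rescaling, the number in the sample title as a replicate block, sample weights, a robust fit, other thresholds, leaving out each sample, and count models on the recovered reads with edgeR 4.0.16 and DESeq2 1.42.0. Coordinates are from GENCODE release M21 on GRCm38, the build the submitters' processing notes name, and count from 1.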

Results

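Gene expression was measured in distal ileal tissue of BALB/c mice, in 6 libraries from PBS controls and 6 from the group treated with P. gingivalis, an oral bacterium associated with periodontitis. The libraries are called PBS replicates 1 to 6 and P. gingivalis replicates 1 to 6, after the numbers in their titles. Recovered depth ran from 7610970 to 10378841 reads in the PBS libraries and from 6553306 to 9875045 reads in the P. gingivalis libraries. Values are normalized counts, given as mean ± SD with n = 6 per group, and differences are P. gingivalis minus PBS on the log2(normalized count + 1) scale with their standard error (SE).

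By its title, the series asks about a link between P. gingivalis and inflammation of the intestine. The clearest contrast lay in genes of fat tissue, which had lower means after P. gingivalis. Fasn, the fatty acid synthase, averaged 3977 ± 1690 in PBS and 1223 ± 352 after P. gingivalis, a log2 difference of -1.62 (SE 0.28). Scd1, a stearoyl-CoA desaturase, averaged 7502 ± 4217 and 573 ± 750, a difference of -4.82 (SE 0.87). For both genes all 6 P. gingivalis libraries lay below the lowest PBS library. Over all 15025 genes tested, 25 had no overlap between the groups, where chance gives 32.5. Neither passed the test over all genes (limma adjusted p = 0.165 for each).

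The rule for named genes gave 4 further genes with lower means. Thrsp, a regulator of lipid synthesis, differed by -3.54 (SE 0.63), Tusc5, a protein of fat cells, by -2.16 (SE 0.38), Fabp4, the fat cell fatty acid binding protein, by -2.68 (SE 0.54) and Cdo1, a cysteine dioxygenase, by -1.17 (SE 0.23). Their limma adjusted p-values were between 0.165 and 0.228. The 6 genes with higher means differed by less. Bcl6, a transcriptional repressor, averaged 77.8 ± 20.6 in PBS and 129.9 ± 14.6 after P. gingivalis, a difference of 0.76 (SE 0.15, limma adjusted p = 0.215). Fkbp5, a glucocorticoid-responsive co-chaperone, differed by 0.66 (SE 0.16), E2f3, a cell cycle transcription factor, by 0.42 (SE 0.12) and Mcm3, part of the replicative helicase, by 0.41 (SE 0.11). Yars, a tyrosyl-tRNA synthetase, differed by 0.35 (SE 0.09) and Hells, a chromatin remodelling helicase, by 0.31 (SE 0.08). None of these 5 passed, with limma adjusted p-values from 0.336 to 0.630.

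**Figure D1:**
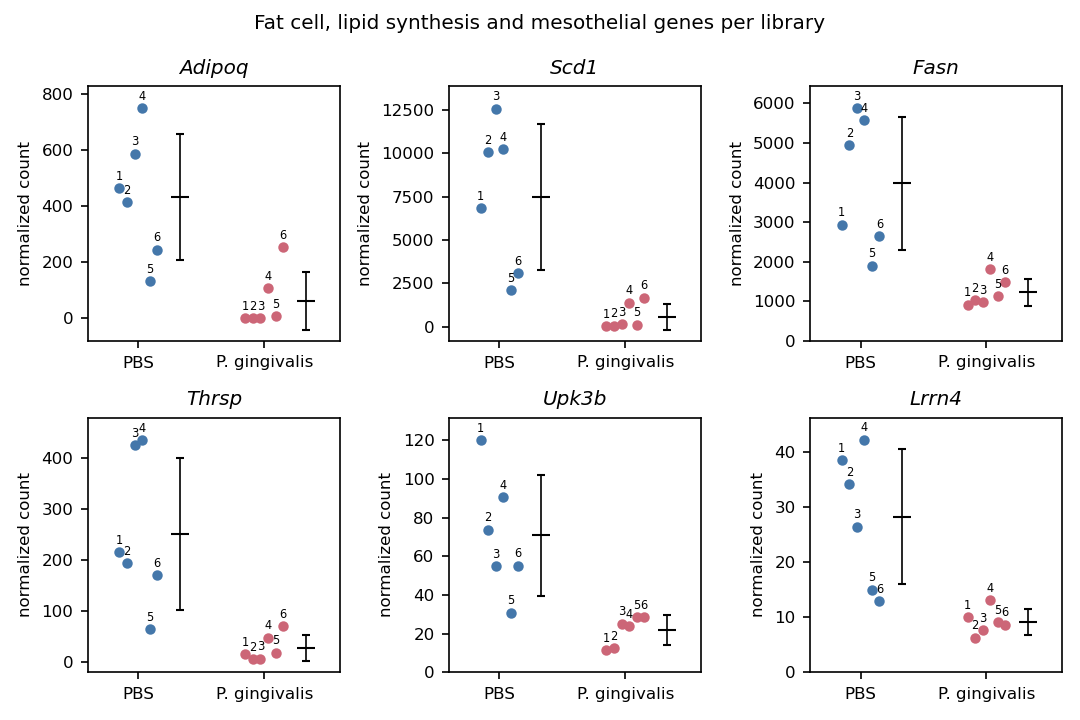
Normalized counts (vertical axes, linear) of Adipoq, Scd1, Fasn, Thrsp, Upk3b and Lrrn4 in PBS and P. gingivalis libraries; points are libraries numbered by replicate, and black marks give the mean with its SD. Adipoq had no reads in P. gingivalis replicates 1, 2 and 3 and reached 254 in replicate 6, against 132 to 751 in PBS.

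Over all 15025 genes tested, limma called 0 genes higher and 0 lower at an adjusted p of 0.05, with 560 genes at an unadjusted p under 0.05 where chance gives 751. The smallest adjusted p was 0.151, for Apoc1, an apolipoprotein. On the recovered reads edgeR also called 0 of 14907 genes, with 542 at an unadjusted p under 0.05, and DESeq2 called 33 of 18561, 3 higher and 30 lower, with 703 at an unadjusted p under 0.05. The DESeq2 calls included Fasn (adjusted p = 5.2e-06), Tusc5 (adjusted p = 8.9e-05), Upk3b (adjusted p = 0.000849) and Bcl6 (adjusted p = 0.00845). The other genes it called higher were the 18S ribosomal RNA gene Rn18s-rs5 and the gene model Gm10800. Of the adipocyte list fixed in advance, DESeq2 called 3 members, Scd1, Thrsp and Cidec. It did not call Adipoq, Plin1, Cfd, Fabp4, Retn, Lep, Lpl or Car3. With sample weights limma called 1 gene higher and 19 lower, 9 of these 20 also called by DESeq2. Leaving out 1 library changed the limma count in 4 cases. Without P. gingivalis replicate 6 there were 1 higher and 52 lower calls, 21 of these 53 genes also called by DESeq2. Among the lower genes were Adipoq, Plin1, Cfd, Lep, Retn and Car3, all members of the adipocyte list fixed in advance. All but Retn were singled out from it after their values were seen. Adipoq stood at 254 in that replicate, against 0 to 106 in the other P. gingivalis libraries. There were 7 lower calls without PBS replicate 5, 1 higher call (Bcl6) without PBS replicate 6 and 1 lower call (Alb, albumin) without P. gingivalis replicate 2.

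The positions of the main genes on GRCm38 are as follows. Fasn lies on chromosome 11 from 120805846 to 120824547 and Scd1 on chromosome 19 from 44394455 to 44407879. Adipoq lies on chromosome 16 from 23146536 to 23158028 and Bcl6 on the same chromosome from 23965052 to 23988852. Fabp6 lies on chromosome 11 from 43596049 to 43601540. All 5 are annotated as protein coding genes, and the values cover whole genes, without regard to exon or isoform.

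Among the lists fixed in advance, the adipocyte list was lower by camera (adjusted p = 7.4e-29). All 17 tested members had negative differences, with a median of -3.12. Of these, 13 were lower adjusted over the list alone and 0 over all genes. The call was lost with an estimated correlation between genes (adjusted p = 0.0633 with an estimated correlation), and was made by fry (adjusted p = 0.0362). Beside Scd1, Thrsp and Fabp4, the member with the next smallest p was Retn, the fat cell hormone resistin, which averaged 81.3 ± 42.9 and 8.47 ± 12.8. Adipoq, the fat cell hormone adiponectin, is a member singled out after its values were seen. It averaged 432 ± 225 in PBS and 61.2 ± 103 after P. gingivalis. Adipoq, Plin1, Cfd, Lep and Retn had no reads in the same 3 libraries, P. gingivalis replicates 1, 2 and 3. A count of 0 allows up to 3 reads per library, so these genes were not detectable there at this depth.

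Markers of the mesothelium, the cell layer covering gut and mesentery, also had lower means after P. gingivalis. Upk3b averaged 70.8 ± 31.3 in PBS and 21.7 ± 7.78 after P. gingivalis, and Lrrn4 averaged 28.3 ± 12.3 and 9.18 ± 2.33. The mean of 8 mesothelial genes, chosen after the values were seen, differed by -1.27 log2 units, from 4.41 ± 0.45 in PBS to 3.14 ± 0.35 after P. gingivalis. The smooth muscle list was also lower by camera (adjusted p = 1.2e-10; adjusted p = 0.691 with an estimated correlation), with negative differences for 25 of 26 members. Its examples were Actg2, an enteric smooth muscle actin, at -0.67 (SE 0.24), Des, desmin, at -0.52 (SE 0.22), and Hspb6, a small heat shock protein, at -0.54 (SE 0.20). P. gingivalis replicate 6 stood apart from its group, with a smooth muscle list mean of 9.94 log2 units against 9.01 to 9.70 in PBS and 8.52 to 9.31 in the other P. gingivalis libraries, and the highest Actg2 of the 12 libraries, at 2099.8.

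**Figure D2:**
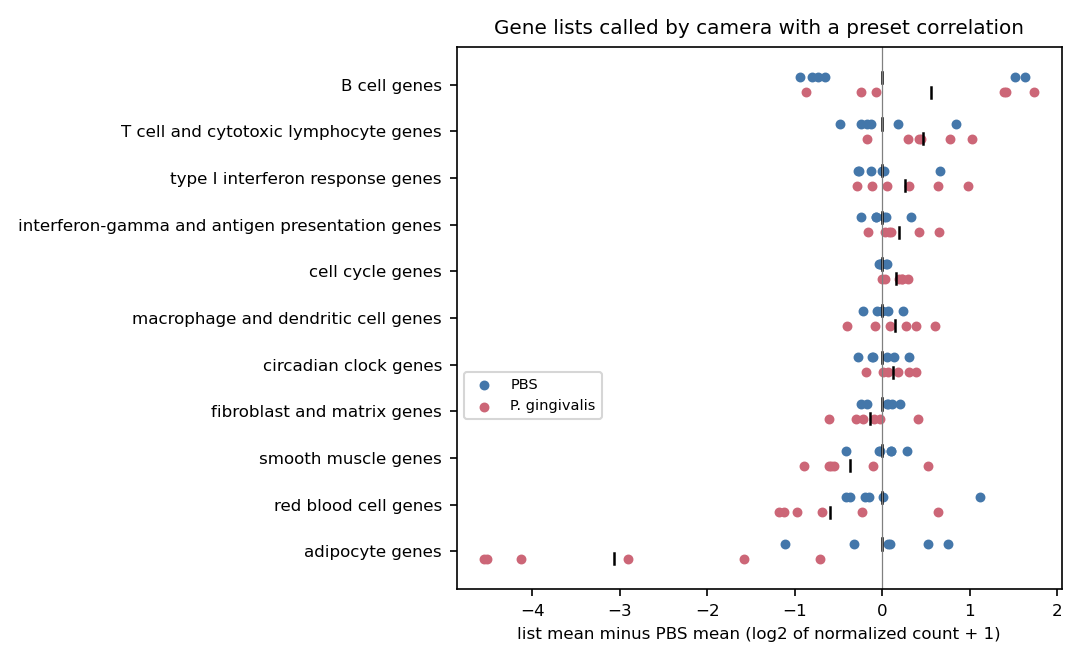
Mean log2(normalized count + 1) of each gene list called by camera, minus the PBS mean of that list (horizontal axis, log2 units); points are libraries, and black lines are group means. The adipocyte list had a mean difference of -3.07, and the B cell list a mean difference of 0.56 with both groups spread widely.

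Camera called 7 lists higher and 4 lower of the 35 tested, and with an estimated correlation it called 0 higher and 0 lower. Fry called 1 list. Leaving out PBS replicate 6 gave 11 higher and 8 lower lists. Lower lists numbered 7 without PBS replicate 2, 7 without P. gingivalis replicate 2 and 2 without PBS replicate 3. By exact permutation of list means, 3 lists had an unadjusted p under 0.05, the adipocyte (exact p = 0.00433), cell cycle (exact p = 0.0216) and NF-kB and inflammatory cytokine lists (exact p = 0.0368), and 0 passed after adjustment.

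The cell cycle list was higher by camera (adjusted p = 2.7e-11; adjusted p = 0.297 with an estimated correlation), with positive differences for 30 of 34 members, a median of 0.15 and 0 members past the threshold over all genes or adjusted over the list alone. Its examples beside Mcm3 were Cdc6, a replication licensing factor, at 0.42 (SE 0.15), Bub1, a mitotic checkpoint kinase, at 0.28 (SE 0.12), and Rrm2, a ribonucleotide reductase subunit, at 0.28 (SE 0.13).

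Lymphocyte and interferon lists were higher by camera as well. The T cell and cytotoxic lymphocyte list had positive differences for all 20 tested members (median 0.44, adjusted p = 2.0e-07; adjusted p = 0.595 with an estimated correlation). Cd4, the helper T cell coreceptor, averaged 50.6 ± 20.5 and 71.5 ± 17.0, and Tcf7, a T cell transcription factor, 40.7 ± 14.5 and 52.97 ± 6.66. In the type I interferon list 34 of 37 members had positive differences (median 0.27, adjusted p = 2.0e-06; adjusted p = 0.719 with an estimated correlation). Zbp1, a nucleic acid sensor, differed by 0.66 (SE 0.25) and Trim30a by 0.48 (SE 0.22), while the interferon-induced gene Ifi27l2a went the other way at -0.87 (SE 0.29). The interferon-gamma and antigen presentation list had 35 of 40 positive members (adjusted p = 9.0e-06; adjusted p = 0.691 with an estimated correlation), among them the GTPase genes Tgtp2 at 0.60 (SE 0.27) and Gbp8 at 0.42 (SE 0.24). In the B cell list 24 of 25 members were positive (adjusted p = 4.0e-05; adjusted p = 0.719 with an estimated correlation), including Blnk, a B cell receptor adaptor, at 0.41 (SE 0.15). Its list mean lay between 6.13 and 6.49 log2 units in PBS replicates 1 and 6 and P. gingivalis replicates 3, 4 and 6, and between 3.80 and 4.68 in the other 7 libraries (exact permutation p = 0.327 for the group difference). Over all genes and adjusted over the list alone, 0 members of these 4 lists passed.

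The remaining 4 lists lost their call without some libraries. The macrophage and dendritic cell list (adjusted p = 0.0130; adjusted p = 0.719 with an estimated correlation) had 21 of 28 positive members, including Flt3, a dendritic cell growth factor receptor, at 0.55 (SE 0.21). The circadian clock list (adjusted p = 0.0162; adjusted p = 0.719 with an estimated correlation) had 15 of 20 positive members, with the clock repressor Cry1 at 0.46 (SE 0.15). The fibroblast and matrix list was lower (adjusted p = 0.0127; adjusted p = 0.719 with an estimated correlation), with 24 of 32 negative members, among them Lox, a collagen cross-linking oxidase, at -0.66 (SE 0.21) and Sparc at -0.41 (SE 0.14). The red blood cell list was lower (adjusted p = 0.0162; adjusted p = 0.691 with an estimated correlation), with 5 of 6 negative members and Hbb-bt, a beta-globin gene, at -1.69 (SE 0.53) the member lower adjusted over the list alone. The macrophage and dendritic cell list was not called without PBS replicates 4 or 5 or P. gingivalis replicates 1 or 6 (adjusted p up to 0.453), nor the circadian list without PBS replicates 1, 2 or 3 or P. gingivalis replicates 1, 2 or 5 (up to 0.147). The fibroblast list was not called without PBS replicates 3, 4 or 5 or P. gingivalis replicates 2 or 3 (up to 0.842), nor the red blood cell list without PBS replicate 3 or P. gingivalis replicates 2, 3 or 6 (up to 0.183). In lists without a call, Slpi, a protease inhibitor of mucosal defence, at -1.16 (SE 0.32) and Phlda3, a p53 target, at -1.06 (SE 0.23) passed adjusted over their list alone, and DESeq2 also called Phlda3.

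None of the inflammatory, antimicrobial and barrier genes fixed in advance and tested passed in limma. Reg3b, an antimicrobial lectin, averaged 6944 ± 4566 in PBS and 13568 ± 7622 after P. gingivalis, a difference of 1.07 (SE 0.55, limma adjusted p = 0.992), and Reg3g differed by 0.56 (SE 0.35). Il1b, the cytokine interleukin 1 beta, averaged 20.4 ± 5.90 and 27.8 ± 11.7, and Muc2, the main intestinal mucin, 26017 ± 7577 and 31630 ± 10455. The junction genes Ocln, Tjp1 and Cldn2 differed by -0.10 (SE 0.13), 0.00 (SE 0.11) and 0.03 (SE 0.36). Igha, the immunoglobulin A heavy chain, differed by 0.15 (SE 0.16). Tnf averaged 9.64 ± 2.78 and 9.82 ± 1.95 and Lcn2 7.98 ± 2.02 and 7.33 ± 2.78, both below the filter. Saa1, an acute phase protein, averaged 2.63 ± 2.07 and 7.32 ± 10.8, also below the filter. Il17a had 0 reads in all 12 libraries, Ifng 1 read in PBS and Il6 1 read in each group, so differences in these cytokines were not detectable at this depth.

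**Figure D3:**
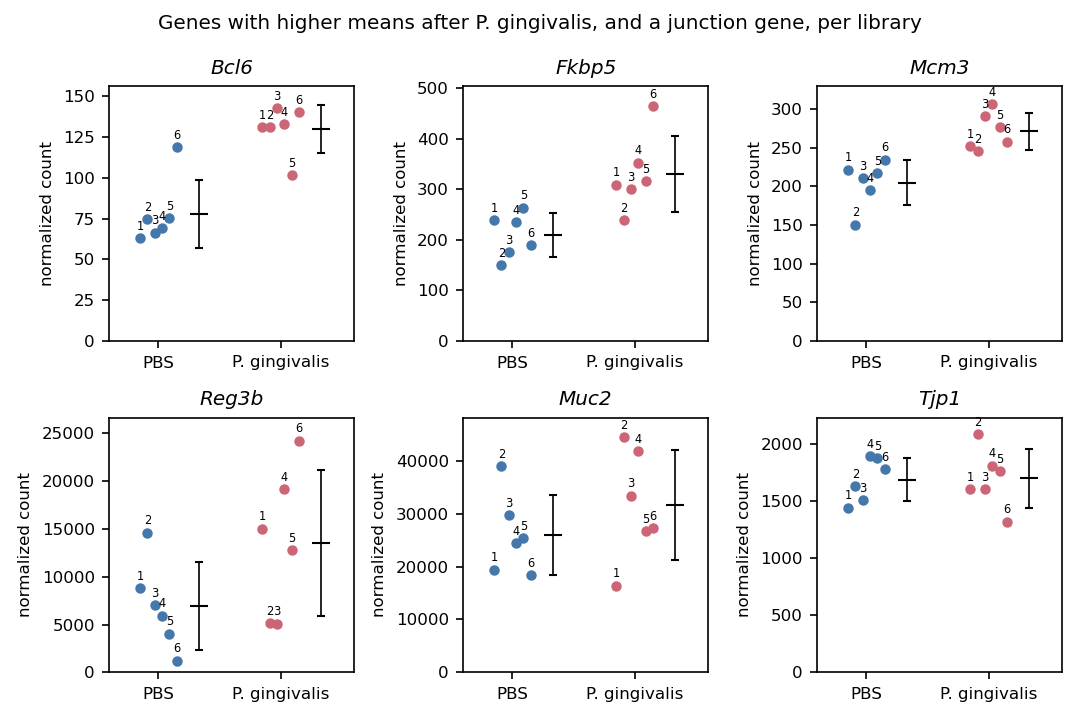
Normalized counts (vertical axes, linear from 0) of Bcl6, Fkbp5, Mcm3, Reg3b, Muc2 and Tjp1 in PBS and P. gingivalis libraries; points are libraries numbered by replicate, and black marks give the mean with its SD. Bcl6 lay between 62.8 and 118.8 in PBS and between 101.7 and 142.5 after P. gingivalis, while Tjp1 lay between 1444 and 1897 in PBS and between 1322 and 2091 after P. gingivalis.

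Fabp6, the ileal bile acid binding protein, split the libraries across both groups. It stood at 4.32 normalized counts in PBS replicate 6, 2.52 in P. gingivalis replicate 1 and 16.002 in P. gingivalis replicate 5, and between 11246 and 69383 in the other 9 libraries. Its group difference was -2.23 (SE 2.75, limma adjusted p = 0.992). Fabp1, a fatty acid binding protein of the upper small intestine, stood at 16938, 26745 and 21996 in the same 3 libraries and at most 1821 in the others. P. gingivalis replicate 6 lay at the opposite end, with Fabp1 at 18.3 and Lct, lactase, at 0.870. The 3 libraries also had the highest T cell list means (5.42, 5.59 and 5.35 log2 units) and type I interferon list means (7.49, 7.81 and 7.47), as well as the highest interferon-gamma list means (7.85, 8.18 and 7.94) and circadian clock list means (8.399, 8.49 and 8.402). With a gut position score in the model, chosen after the values were seen, the mean difference of the circadian clock list went from 0.13 to 0.07 log2 units and that of the type I interferon list from 0.26 to 0.16.

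**Figure D4:**
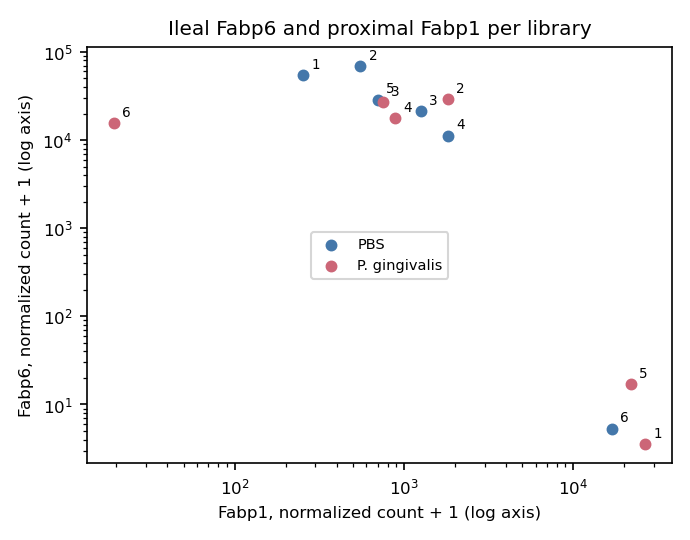
Fabp6 against Fabp1, each as normalized count + 1 on a log axis, with 1 numbered point per library and the group in colour. PBS replicate 6 and P. gingivalis replicates 1 and 5 sit at low Fabp6 (2.52 to 16.002 before the 1 is added) and high Fabp1, apart from the other 9 libraries.

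Neither leading principal component separated the groups past the threshold with all 12 libraries. The first held 38.7% of the variance, and its scores ran from -30.4 to 31.7 in PBS and from -54.7 to 54.5 after P. gingivalis (exact permutation p = 0.338, n = 6 per group). The second held 16.5% (exact permutation p = 0.474). On this component P. gingivalis replicates 2 and 3, at -41.6 and -15.7, lay below the PBS range of -13.1 to 6.58. Replicates 1, 5 and 6 lay above it, at 29.8, 11.8 and 38.5, and replicate 4 within it, at 4.90. Components computed anew after leaving a library out are other axes. On the second of these the group means differed without P. gingivalis replicate 2 (exact permutation p = 0.00216) and without P. gingivalis replicate 6 (exact permutation p = 0.0455). Over all libraries left out in turn, its exact permutation p ran from 0.00216 to 0.790, without adjustment. Ribosomal RNA shares also varied. Rn18s-rs5 took 4.597% of reads in P. gingivalis replicate 4 and 0.629% in replicate 2, and at most 0.00561% elsewhere. Mitochondrial ribosomal RNA took 0.836% to 10.9% of reads.

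**Figure D5:**
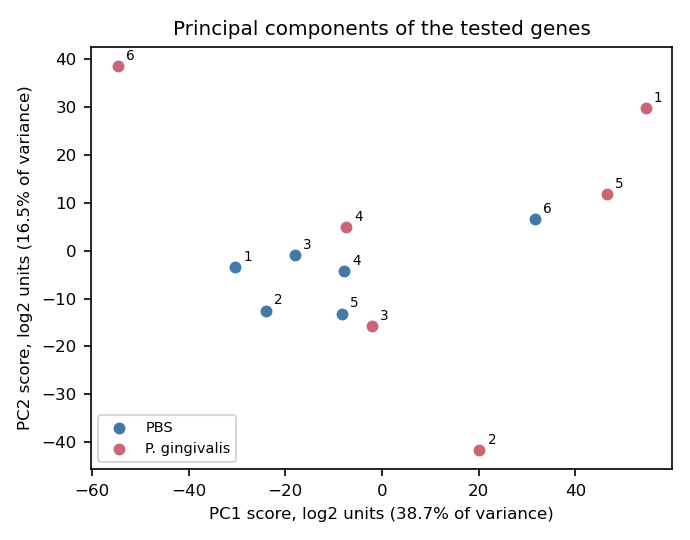
Scores of the 12 libraries on the first (38.7% of variance, horizontal axis) and second (16.5%, vertical axis) principal components of log2(normalized count + 1), in log2 units, with points numbered by replicate. PBS replicate 6 lies at 31.7 on the first component beside P. gingivalis replicates 1 and 5, and P. gingivalis replicate 6 lies at -54.7.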

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

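The tests of fat tissue, mesothelium, gut position and Fabp6 below were chosen after the values they use were seen, and the mesothelial test was narrowed to 6 genes after its first result; the tests of other splits and of list calls with a score in the model were fixed before their results (those with an estimated correlation after), though after the high T cell and interferon means of 3 libraries had been seen. A library far from the other 5 of its group appeared in 10 of 142 groups of values, where chance gives about 1 in 20.

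PBS replicate 6 gave 6 of these 10 values. Its Fabp6 was 4.32 against 11246 or more in the other PBS libraries, and its Bcl6 was 118.8 against 62.8 to 75.2. Trim30a stood at 149.0 there against 73.6 to 92.3, and Cry1 at 232 against 120.0 to 149.6. The mean of its type I interferon list was 7.49 log2 units against 6.56 to 6.85, and its first component score was 31.7 against -30.4 to -7.86. In P. gingivalis replicate 5, Bcl6 was 101.7 against 131.1 to 142.5 in the other P. gingivalis libraries. Phlda3 was 41.8 in P. gingivalis replicate 6 against 23.5 to 28.5. The mitochondrial ribosomal RNA mt-Rnr2 was 789835 in P. gingivalis replicate 1 against 94119 to 190146. The red blood cell list mean was 7.69 log2 units in PBS replicate 3 against 6.16 to 6.58.

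The adipocyte list was lower after P. gingivalis by camera with a preset correlation (adjusted p = 0.0633 with an estimated correlation), and 3 treated libraries had no Adipoq reads. A drop in lipid synthesis alone, within an unchanged number of fat cells, is argued against by the 15 tested members that are not lipid synthesis genes, whose mean was 8.68 ± 0.62 log2 units in PBS and 5.77 ± 1.62 after P. gingivalis (n = 6 each, exact permutation p = 0.00433). The whole list was already known to be lower, with the same exact permutation p, so this p is no separate support. Less fat tissue in the pieces is consistent with the ratios of fat genes: over the 9 libraries with Adipoq, the mean log2 ratio of Cfd, Plin1 and Car3 to Adipoq had an SD of 0.19, against 2.05 for log2 Adipoq itself. Whether less mesentery came with the pieces stays open, since 6 mesothelial genes were lower (exact permutation p = 0.00216) but chosen after values were seen, and P. gingivalis replicate 6 had a fat identity mean of 7.35 log2 units, within the PBS range, with a mesothelial mean of 3.52, below every PBS library. Loss of mesenteric fat in treated mice and closer trimming at dissection cannot be told apart, since no library measures another fat depot or the trimmed tissue.

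Fabp6 was nearly absent in 3 libraries. A response to P. gingivalis alone is argued against by PBS replicate 6, at 4.32. Pieces taken further up the intestine are a candidate explanation: a score of 6 proximal minus 5 distal genes was compared with hormone genes not used in it (Gip, Cck and Ghrl against Pyy, Gcg and Nts) over the 9 other libraries, the single relation computed. Spearman's rho was 0.93 (exact permutation p = 0.00075) and Pearson's r 0.91 (exact permutation p = 0.000728), and r was 0.68 without the 2 libraries farthest from the median. This relation leaves out the 3 libraries themselves, so its p does not bear on them directly. The mean of Gip, Cck and Ghrl minus that of Pyy, Gcg and Nts was -0.59 log2 units in PBS replicate 6. It was 0.99 and -0.26 in P. gingivalis replicates 1 and 5, and -5.06 to -2.26 in the other 9 libraries. The group means of the position score differed by less than its spread (0.74 ± 3.68 and 2.03 ± 5.53, n = 6 each, exact permutation p = 0.649).

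T cell, type I interferon and cell cycle lists were higher after P. gingivalis by camera with a preset correlation. With the gut position score in the model camera still called the T cell (adjusted p = 2.7e-06), interferon (adjusted p = 1.3e-05) and cell cycle lists (adjusted p = 1.2e-10), but not with an estimated correlation (adjusted p = 0.461, 0.461 and 0.281), and mean log2 differences went from 0.46 to 0.38, 0.26 to 0.16 and 0.16 to 0.15. With the B cell list score in the model, read as lymphoid follicles, it still called the T cell (adjusted p = 1.4e-05, mean 0.36) and cell cycle lists (adjusted p = 7.0e-09, mean 0.14), again not with an estimated correlation (adjusted p = 0.786 and 0.442). A kept call was meant to count against each explanation, but 75 of 100 splits of the libraries gave as many list calls as the real 11 (highest other count 23), so it does not decide, and position and follicles stay open. Chance could not be excluded, and the treatment stays open as a hypothesis.

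For single genes the real split called 0, a count that all 100 of 100 splits reach whatever the data, so it says nothing on chance. At an unadjusted p under 0.05 the real split had 560 genes, and 44 of 100 splits had as many, with a highest other count of 4009, so chance could not be excluded. The split with the highest count of called genes, 564, set PBS replicates 4, 5 and 6 and P. gingivalis replicates 1, 2 and 5 against the rest, with all 3 libraries of little Fabp6 on that side. Mean position scores were 4.405 on that side and -1.64 on the other, which points to a structure of the samples other than the groups; no test of position as its source was run.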

How the results depend on the processing

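Settings with the position score, without libraries chosen by Fabp6, position or 18S RNA, and the exact permutation of list means were chosen after seeing the data. The counts of 0 higher and 0 lower genes held with a pseudocount of 0.5, both other filters, both rescalings, the robust fit and edgeR. An adjusted p of 0.1 and a minimum change of 1 log2 unit were applied to the main limma fit. Its smallest adjusted p was 0.151, so these 2 settings could only give 0 and test nothing further. There was 1 lower gene (Apoc1) with a pseudocount of 5, 1 higher and 19 lower with sample weights, and 3 higher and 30 lower with DESeq2. Leaving out each sample gave 0 to 1 higher and 0 to 52 lower genes. The position score as a covariate gave 1 lower gene (Apoc1), leaving out the 3 libraries with little Fabp6 gave 1 higher (Bcl6), leaving out these and P. gingivalis replicate 6 gave 1 higher and 8 lower, and leaving out the 2 libraries with much 18S RNA gave 0 and 0. The causes were not tested. No scaling moved the median log2 difference of all genes by more than 0.1.

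List counts of 7 higher and 4 lower became 0 and 0 with an estimated correlation, 0 and 1 with fry, and 0 and 0 by exact permutation. Leaving out each sample gave 6 to 11 higher and 2 to 8 lower lists. There were 7 lower lists with the position score and 10 lower without the 3 libraries with little Fabp6, and 12 higher without the 2 with much 18S RNA. The cause was not tested. The macrophage and dendritic cell list went from a mean of 0.141 to 0.0414 without the 3 libraries with little Fabp6, and lost its call. It turned to a mean of -0.0870 without the 4 libraries at the position ends. With a mean of at least 50 the T cell and red blood cell lists had too few members to test. Exact permutation p-values of both components stayed above 0.05 with the other pseudocounts, filters and rescalings. Leaving out each sample, with components computed anew, gave 0.0758 to 0.665 for the first component and 0.00216 to 0.790 for the second. The second lay under 0.05 only without P. gingivalis replicate 2 (0.00216) or replicate 6 (0.0455).

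Signs turned for 6 genes that had not passed, with differences over all 12 libraries of 0.37 for Il1b, 0.26 for Muc2, 0.15 for Igha, -0.10 for Ocln, 0.03 for Cldn2 and 0.00 for Tjp1. Leaving out each sample gave Tjp1 from -0.0596 to 0.0726 and Cldn2 from -0.199 to 0.224, and without a change of sign Il1b from 0.231 to 0.498, Muc2 from 0.142 to 0.431, Igha from 0.0529 to 0.268 and Ocln from -0.163 to -0.00853. Tjp1 was -0.0192 with the position score and -0.102 without the 2 libraries with much 18S RNA. Cldn2 was -0.0521 with sample weights and -0.0163 without those 2 libraries, where Muc2 was -0.00456. Igha was -0.00517 without the 3 libraries with little Fabp6, and without the 4 at the position ends Igha was -0.0779, Il1b -0.0618 and Ocln 0.0245. The causes were not tested.

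With the title number as a replicate block, limma called 0 higher and 0 lower genes, and camera 7 higher and 4 lower lists. No pairing by number was seen: residual correlations of same-numbered libraries exceeded 0.1 in 0 of 6 pairs, and 0 of 12 libraries correlated best with their own number. A pairing weaker than the differences along the first component could go unseen in these correlations. Depth leaves cytokines with few reads, such as Il6, Ifng and Il17a, untested.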

Other observations

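The glucocorticoid list was chosen after Bcl6 and Fkbp5 were seen and the spread was compared after the components were seen; the tests of the 2 hypotheses were fixed before their results.

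Other gene groups showed no call by camera, and several had a common direction. All 10 mitochondrially encoded genes tested had positive differences (adjusted p = 0.0517), while 22 of 25 cholesterol synthesis genes (adjusted p = 0.230) and 17 of 21 enteric neuron and glia genes (adjusted p = 0.0845) had negative ones. In the libraries of little Fabp6 (PBS replicate 6, P. gingivalis replicates 1 and 5), mitochondrial list means were highest (10.6, 11.1 and 10.5 log2 units). Cholesterol synthesis means were lowest there (8.44, 8.39 and 8.46). With the position score in the model, chosen after values were seen, mean differences went from 0.27 to 0.15 for mitochondrial genes. Those for cholesterol synthesis went from -0.095 to -0.005, with camera's direction up. Tight junction and adherens junction genes had 21 negative members of 30 (adjusted p = 0.0906), goblet cell and mucus genes 14 of 19 (adjusted p = 0.0845), and ileal bile acid handling genes 9 of 10 (adjusted p = 0.119). Bile acid list means stood at 7.78, 7.40 and 7.85 log2 units in the libraries of little Fabp6, against 9.68 to 10.79 in the others. The 5 distal genes of the position score, Fabp6, Slc10a2, Slc51a, Slc51b and Fgf15, are all tested members of this list. The score is thus partly built from the list, so the list's values with the score in the model decide nothing on position or treatment. With the position score the mean difference of this list went from -0.71 to -0.41. Camera then called it lower (adjusted p = 0.0310; adjusted p = 0.673 with an estimated correlation). NF-kB and inflammatory cytokine genes had 18 positive members of 27 (adjusted p = 0.0906), and Th17 and group 3 innate lymphoid genes 10 of 14 (adjusted p = 0.0906). Paneth cell genes had 11 positive of 19 (adjusted p = 0.799) and crypt stem cell genes 10 negative of 18 (adjusted p = 0.832). Endoplasmic reticulum stress genes had a median of 0.01 and a mean of -0.01 while camera's direction was up (adjusted p = 0.872).

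Within the lipid synthesis genes the members differed in direction. Acaca, an acetyl-CoA carboxylase, differed by -0.92 (SE 0.23) and Me1, malic enzyme, by -0.90 (SE 0.28). Elovl6, a fatty acid elongase, stood at 699 ± 19.0 and 779 ± 58.9, and Srebf1, the transcription factor of the pathway, at 652 ± 170 and 688 ± 289 (n = 6 each). None of the 4 passed in limma, and DESeq2 called Acaca (adjusted p = 0.0340).

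Groups did not overlap for 25 of 15025 genes, 14 higher and 11 lower after P. gingivalis, where chance gives 0.216%, or 32.5 genes.

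A hypothesis was that Bcl6 and Fkbp5, both responsive to glucocorticoids, were higher through a glucocorticoid response. The mean of 12 other target genes, among them Tsc22d3 (0.27), Zbtb16 (0.39), Mt1 (-0.42) and Glul (-0.45), differed by -0.04 log2 units (exact permutation p = 0.771). A shared rise of these targets was therefore not seen, which weighs against a broad response of the size seen for Fkbp5.

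Libraries lay farther from their own group mean after P. gingivalis, at a mean distance of 52.3 over all components against 37.5 in PBS (exact permutation p = 0.0433). Another hypothesis was that this spread may reflect gut position. With the position score removed from every gene, the mean distances to the group mean went from 37.5 and 52.3 to 32.1 in PBS and 39.4 after P. gingivalis, and the exact permutation p from 0.0433 to 0.113. The gap between the groups narrowed, and the p no longer lay under 0.05. The score follows the first component and varied more after P. gingivalis (SD 5.53 against 3.68), so its removal narrows the gap whatever it stands for, and the part of position stays open.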
